A study of Mus musculus with 14 samples.

How the data were processed

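Bulk RNA-seq was analysed from 14 mouse libraries in 2 experiments. The first holds 8 libraries of inguinal white adipose tissue (iWAT) from 8-week-old mice, 2 for each of 4 groups: Hmgcs2 +/+ (CTL) and Hmgcs2 -/- (KO) mice, each at 23 °C (RT) or 4 °C (Cold). The second holds 6 libraries of the stromal vascular fraction (SVF) of iWAT from wild-type males at postnatal day 21, 3 given water and 3 given 1,3-butanediol (1,3BD). Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with the KAPA mRNA HyperPrep kit. The submitters' processing notes name the build mm10 and the tools edgeR and DESeq2, without versions. The aligner, the counter and its strand setting, the length of the cold exposure, the feeding state, the hour of harvest and the sex of the iWAT mice are not given in the sources used here. The labels do not say that replicates are separate animals, so every p-value below measures spread between these samples only.

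The deposited values of both tables are a signal, not counts: each column holds whole reads divided by 1 size factor per library, although the deposited tables are named as raw counts. Multiplying each column by its factor returned whole reads for 100% of values within a tolerance of 0.001, with a largest deviation of 2.6e-09 in iWAT and 1.7e-09 in SVF. The factors equal median-of-ratios size factors recomputed from those reads, with a largest relative difference of 2.6e-15 and 3.3e-15. The recovered totals are 13.3 to 15.3 M reads per iWAT library and 15.9 to 19.1 M per SVF library. At this depth a gene near the filter's minimum count of 10 carries a wide counting error, and counting intervals are given for groups with 1 to 3 reads. The tables list 33164 genes for iWAT and 27827 for SVF, and 17187 and 13857 passed edgeR's filterByExpr by group. Gene IDs, coordinates and missing symbols came from GENCODE M21 (mm10). It named 1071 of 1098 iWAT genes and 805 of 817 SVF genes listed without a symbol.

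The design fixed before the data were examined (comparisons, gene lists, rule for named genes and most alternatives) assumed counts and an edgeR quasi-likelihood test. Because the values are a signal, the test was changed to limma 3.58.1 in R 4.3.3: log2(value + 1), 1 group-means model per experiment, empirical Bayes moderation with a mean trend, and Benjamini-Hochberg adjustment with a threshold of 0.05. The change was a choice, since the edgeR test could also be run on the recovered reads. The added pseudocount of 1 understates fold changes of low genes. The 5 iWAT comparisons were cold against RT in CTL, cold against RT in KO, KO against CTL at RT, KO against CTL in the cold, and the genotype by temperature interaction, which is the cold change in KO minus the cold change in CTL. The SVF comparison was 1,3BD against water. The edgeR 4.0.16 test on the recovered reads with TMM factors called 6657, 952, 7023, 10067, 5131 and 6834 genes in these 6 comparisons in that order. Means are of deposited values with SD, and log2 fold changes come from the model with SE, n = 2 per iWAT group and n = 3 per SVF group.

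In all, 24 gene lists were fixed, and 23 of them were tested in at least 1 experiment with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. A list needed at least 3 measured members, which the neutrophil list did not have. Of the 24, 12 were meant for both experiments: thermogenic and beige adipocyte genes, ketone body metabolism, fatty acid oxidation, oxidative phosphorylation, de novo lipogenesis, mature adipocyte genes, extracellular matrix, macrophages, T and B lymphocytes, endothelial cells, skeletal muscle and erythroid cells. Lists for iWAT alone were lipolysis and adrenergic signalling, cholesterol synthesis, creatine and calcium cycling, and mammary and other epithelium. Lists for SVF alone were Dpp4-positive interstitial progenitors, Icam1-positive and F3-positive preadipocytes, beige adipocyte progenitors, pericytes and smooth muscle, Schwann cells, cell cycle, immediate early and dissociation stress, and neutrophils. A member count at an adjusted p over all genes is given with the count adjusted over the list alone. Beside each list call stands its adjusted p with a correlation estimated for each list.

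Genes are named by 3 rules. These are Hmgcs2 and Ucp1 in any case, up to 4 called members of each list by smallest p, and the 10 called genes with the largest increase and decrease with a mean of at least 1 CPM. Those last genes had every library of one group on the same side of every library of the other. Gene models without a name, ribosomal-protein pseudogenes and mitochondrial genes were passed over. A fold against a group with 0 reads is a lower bound set with 3 reads in each library of that group. Overlap with other annotated genes was checked for each named gene.

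The tests were run on simulated reads with planted changes. In the iWAT setting limma recovered 26.6% of 1.5-fold, 66.2% of 2-fold and 78.1% of 4-fold changes, and 10.6% of its calls were false. With SVF spread the shares were 3.13%, 45.5% and 93.7%, with 9.90% false calls. All recovered changes had the planted direction. Limma called 0 lists in the simulated tables, but genes were drawn there independently of each other. False list calls that come from correlated genes could therefore not be judged from the simulation. Mixed groupings of the SVF libraries, given further below, passed lists without any called gene.

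Alternatives were DESeq2 1.42.0, edgeR with median-of-ratios or TMM factors, limma with TMM scaling or scaling to the library total, no low-count filter, a pseudocount of 0.5 or 5, and an absolute log2 fold change of at least 1. Further ones were a replicate block, leaving out each library in turn, only the 2 compared groups in the model, an estimated inter-gene correlation, and fry. No library was left out of the tests reported first.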

Results

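To ask how loss of the ketogenic enzyme Hmgcs2 and cold exposure shape inguinal fat, RNA-seq was read from 8 iWAT libraries of 8-week-old CTL and KO mice at RT (23 °C) or in the cold (4 °C), n = 2 per group. To ask how an oral ketone source acts on stromal cells of young fat, 6 SVF libraries of 21-day-old mice given water or 1,3BD were read, n = 3 per group. Depth per library in M reads was 14.3 and 14.9 (CTL RT), 13.8 and 14.6 (KO RT), 13.3 and 14.8 (CTL Cold), 13.6 and 15.3 (KO Cold), 15.9, 16.2 and 19.1 (SVF water), and 17.0, 18.2 and 17.2 (SVF 1,3BD). Values are deposited normalized reads, mean ± SD, with log2 fold change ± SE and adjusted p from limma. For a list that passed, the number of members adjusted over the list alone is given where it differs from the number over all genes.

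Hmgcs2 (ENSMUSG00000027875, chromosome 3, 98280435 to 98310738), which makes HMG-CoA for ketone bodies in mitochondria, was low in every KO library. Its reads were 1629 and 1479 in CTL RT, 102 and 94 in KO RT, 2116 and 2490 in CTL Cold, and 266 and 247 in KO Cold. The KO effect on Hmgcs2 was -3.84 ± 0.11 at RT (94.5 ± 7.46 against 1361 ± 89.5, adjusted p = 8.80e-08) and -3.81 ± 0.11 in the cold (222 ± 25.9 against 3118 ± 237, adjusted p = 3.03e-08). Cold raised the remaining Hmgcs2 signal in both genotypes, by 1.20 ± 0.11 in CTL (adjusted p = 5.47e-05) and 1.22 ± 0.11 in KO (adjusted p = 0.000799), and the interaction for Hmgcs2 was 0.03 ± 0.16 (adjusted p = 0.923, or 0.00625 with scaling to the library total).

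Cold raised many genes of heat production and fuel burning in control fat. Of the lists, 18 of 25 thermogenic, 21 of 23 fatty acid oxidation and 35 of 36 respiratory chain genes rose (1 of the last fell). Of 16 fatty acid synthesis genes 13 rose and 1 fell, or 8 and 4 with scaling to the library total. The leptin gene and the receptor genes Adrb3, Hcar1 and Ffar2 fell, as did 8 of 18 T and B cell genes. With an estimated correlation between genes none of these lists passed (adjusted p of 0.505 to 0.655), and the T and B cell list also failed in other settings given below. In all, 3868 genes rose and 2908 fell with cold in CTL, of 17187 tested. Scaled to the library total instead, the median of all genes moved to -0.59 and 1362 genes were higher and 9766 lower, so changes in CTL are relative to the size factors used. Without each library in turn the count stayed between 5133 and 6818.

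Of 25 thermogenic and beige adipocyte genes measured, 18 rose, 0 fell and 7 did not pass (20 up when adjusted over the list alone), with a list median of 2.40 (camera adjusted p = 9.37e-08, and adjusted p = 0.505 with an estimated correlation). Ucp1 (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), the proton leak protein of brown fat mitochondria, went from 338 ± 429 to 27486 ± 3589.6 (7.51 ± 1.11, adjusted p = 0.000807). Its 2 CTL RT libraries differed widely, with 733 and 39 reads. The log2 fold change of Ucp1 was 9.60 without CTL RT 1 and 5.41 without CTL RT 2. Clstn3 rose from 1351 ± 132 to 6279.8 ± 111 (2.22 ± 0.14, adjusted p = 7.27e-06). Letmd1 rose from 580.2 ± 15.3 to 1943 ± 204 (1.74 ± 0.14, adjusted p = 2.13e-05). Cox8b, a cytochrome oxidase subunit of thermogenic fat, rose from 390.1 ± 59.1 to 2054 ± 156 (2.40 ± 0.18, adjusted p = 1.49e-05). Dio2, which activates thyroid hormone, rose from 55.2 ± 20.9 to 3208 ± 534 (5.88 ± 0.53, adjusted p = 4.72e-05).

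Fuel oxidation rose across its lists in CTL. Among 23 fatty acid oxidation genes, 21 rose and 0 fell (median 1.31, camera adjusted p = 1.09e-11, and adjusted p = 0.505 with an estimated correlation). Examples were Ehhadh, the peroxisomal bifunctional enzyme (7932 ± 1598 to 87236 ± 2635, 3.47 ± 0.14, adjusted p = 6.67e-07), and Acaa2 (2.60 ± 0.17, adjusted p = 6.63e-06). Of 36 oxidative phosphorylation genes, 35 rose and 1 fell (median 1.16, camera adjusted p = 2.27e-19, and adjusted p = 0.505 with an estimated correlation). Examples were Cox7b (1714 ± 1.76 to 4437 ± 255, 1.37 ± 0.08, adjusted p = 5.45e-06) and Uqcrc1 (1.53 ± 0.10, adjusted p = 8.50e-06). With scaling to the library total 17 and 30 of these members still rose, with medians of 0.73 and 0.58. In the ketone list 4 of 10 genes rose and 1 fell (camera adjusted p = 0.256), among them Acat1 (1.13 ± 0.10, adjusted p = 3.26e-05) and Slc16a1, a carrier of ketone bodies and lactate (1.59 ± 0.11, adjusted p = 9.80e-06).

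With the size factors used, most de novo lipogenesis genes rose as well, and genes of lipolytic signalling shifted. Of 16 de novo lipogenesis genes 13 rose and 1 fell (14 and 1 when adjusted over the list alone). The median was 0.92 (camera adjusted p = 3.04e-07, and adjusted p = 0.505 with an estimated correlation). These became 8 and 4 with scaling to the library total. Elovl6 rose from 561 ± 79.7 to 6039 ± 886 (3.43 ± 0.13, adjusted p = 4.55e-07), and Scd1, the stearoyl-CoA desaturase, reached 801923 ± 51913 from 100489 ± 2442 (3.00 ± 0.16, adjusted p = 2.61e-06). In the lipolysis and adrenergic list 11 of 15 genes rose and 2 fell (12 and 2 when adjusted over the list alone). The median was 0.62 (camera adjusted p = 0.00185, and adjusted p = 0.505 with an estimated correlation), a split that became 5 and 6 with scaling to the library total. The nuclear receptor gene Nr4a3 rose from 1180.0 ± 202 to 25035 ± 799.6 (4.42 ± 0.14, adjusted p = 2.74e-07) and Adrb2 by 1.75 ± 0.10 (adjusted p = 4.31e-06). In contrast G0s2, an inhibitor of the lipase ATGL, fell from 757 ± 26.6 to 125 ± 5.68 (-2.58 ± 0.10, adjusted p = 5.06e-07). Cholesterol synthesis genes were split, with 9 of 20 up and 6 down (median 0.31, camera adjusted p = 0.256), or 5 and 8 with a median of -0.26 under scaling to the library total.

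White-fat identity genes moved in both directions in CTL. The mature adipocyte list had 5 up, 6 down and 9 not passing, with a median of 0.02, or 1 up and 15 down with a median of -0.56 under scaling to the library total. Its mean was -0.32 and the test's direction down (camera adjusted p = 0.347). Adrb3, the β3-adrenergic receptor, fell from 2409.5 ± 417 to 186 ± 10 (-3.68 ± 0.11, adjusted p = 2.62e-07) and Lep from 119 ± 22.0 to 16.8 ± 6.06 (-2.78 ± 0.22, adjusted p = 2.32e-05). Large falls included the receptors Hcar1 (501 ± 63.2 to 30.3 ± 13.2, -4.07 ± 0.24, adjusted p = 4.00e-06) and Ffar2 (861 ± 89.5 to 59.5 ± 9.19, -3.84 ± 0.14, adjusted p = 4.55e-07), which sense lactate and short-chain fatty acids. The lipid transporter gene Mfsd2a rose from 29.3 ± 6.74 to 3237 ± 79.8 (6.76 ± 0.25, adjusted p = 4.55e-07). Hgd of tyrosine breakdown rose from 32.0 ± 11.8 to 1218 ± 125 (5.25 ± 0.39, adjusted p = 1.48e-05).

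Genes of other cell types also shifted in CTL. T and B lymphocyte genes fell, 8 of 18 with 0 up (12 down when adjusted over the list alone). The median was -0.80 (camera adjusted p = 0.000873, and adjusted p = 0.655 with an estimated correlation). That list did not pass without CTL RT 1 (adjusted p = 0.110) or with scaling to the library total (adjusted p = 0.0765), nor with fry (adjusted p = 0.171). The leukocyte gene Ptprc had 3098 and 1323 reads in CTL RT against 710 and 900 in CTL Cold. Lists that did not pass were macrophages (2 up, 5 down, adjusted p = 0.0951) and extracellular matrix (3 up, 4 down, adjusted p = 0.391). Endothelial cells (6 up, 0 down, adjusted p = 0.0610) had 0 up and 5 down with scaling to the library total. Erythroid cells (3 up, 0 down, adjusted p = 0.0565) had 1 up with that scaling and a median of -0.05. Creatine and calcium cycling genes had 3 up and 0 down (adjusted p = 0.0951), which became 0 and 1 with scaling to the library total. Skeletal muscle genes did not pass (0 of 15, median -1.90, adjusted p = 0.269). Reads of the muscle actin gene Acta1 were 1135 and 1045 in CTL RT, 6 and 11 in KO RT, 2640 and 7 in CTL Cold, and 707 and 14 in KO Cold. The epithelium list had 0 up and 2 down of 11 (adjusted p = 0.0588), and Krt18 had 808 reads in CTL RT 2 and 1 in CTL RT 1. Some of these lists passed with 1 library left out: without CTL RT 1 the epithelium (9.69e-07), erythroid (0.0125) and mature adipocyte lists (0.0264), and without CTL RT 2 the macrophage (0.000123) and endothelial lists (0.000422). Without CTL Cold 1 the muscle (1.68e-05), macrophage (0.0410) and epithelium lists (0.0420) passed, and without CTL Cold 2 the erythroid list (0.00628). Mitochondrially encoded reads were 17.0% and 19.6% of CTL Cold libraries, against 8.38% and 8.70% in CTL RT, and mitochondrial rRNA 4.86% and 5.90% against 0.679% to 0.937% in the other iWAT libraries.

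In KO fat fewer genes passed for cold. Of the 6 lists that passed in CTL, 5 passed in KO too, the thermogenic and lipolysis lists upward in both. The lipogenesis, oxidative phosphorylation and lymphocyte lists passed in the other direction. Of these, oxidative phosphorylation had 2 of 36 and lymphocytes 0 of 18 members called, and neither passed with fry (0.196 and 0.589). Of the lipogenesis and cholesterol lists 8 of 16 and 15 of 20 genes fell, and 9 of 17 macrophage and 6 of 20 matrix genes rose. With an estimated correlation none of these lists passed. Their adjusted p was 0.0700 for cholesterol and 0.258 for lipogenesis, macrophages and matrix. It was 0.523 for the thermogenic, lipolysis and oxidative phosphorylation lists, and 0.627 for lymphocytes. Of the 25 thermogenic genes 4 passed. In all, 438 genes rose and 497 fell, of 17187 tested, or 1004 and 326 with scaling to the library total, which moves the median of all genes to 0.15. The count was 266 without KO RT 1, 206 without KO RT 2, 253 without KO Cold 1 and 314 without KO Cold 2, and 2070 in a model of these 2 groups alone.

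Among the 25 thermogenic genes, 4 rose and 0 fell with cold in KO (7 up when adjusted over the list alone). The median was 0.32 (camera adjusted p = 5.72e-05, and adjusted p = 0.523 with an estimated correlation), and the list did not pass without KO Cold 2 (adjusted p = 0.106) or with fry (adjusted p = 0.230). Ucp1 reads were 190 and 104 in KO RT and 2742 and 9339 in KO Cold (142 ± 61.6 to 5085 ± 3690.0, 5.0 ± 1.11, adjusted p = 0.0359). Its call was lost without any 1 of the KO libraries (adjusted p = 0.148 without KO RT 1, 0.246 without KO RT 2, 0.128 without KO Cold 1 and 0.206 without KO Cold 2) and without the low-count filter (adjusted p = 0.130). Dio2 rose from 25.9 ± 11.7 to 336 ± 259.7 (3.47 ± 0.53, adjusted p = 0.00749, or 0.0804 without KO RT 1). Oxidative phosphorylation genes had 0 up and 2 down (0 and 5 when adjusted over the list alone). The median was -0.19 (camera adjusted p = 1.18e-09, and adjusted p = 0.523 with an estimated correlation). With scaling to the library total 0 rose and 0 fell. Fatty acid oxidation was mixed (2 up, 2 down, adjusted p = 0.0726), but passed without KO Cold 2 (3.66e-06). Ehhadh rose (956 ± 15.0 to 2389.6 ± 408, 1.31 ± 0.14, adjusted p = 0.00165), as did Cpt1a, the gate of mitochondrial fatty acid entry (0.86 ± 0.10, adjusted p = 0.00188). With fry neither the oxidative phosphorylation (0.196) nor the lipolysis list (0.0885) passed. Lipolysis and adrenergic genes had 5 up and 1 down (7 and 1 when adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.00719, and adjusted p = 0.523 with an estimated correlation). Examples were Angptl4 (1.10 ± 0.09, adjusted p = 0.000627) and Nr4a1 (1.09 ± 0.11, adjusted p = 0.00146).

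Lipid synthesis fell in KO fat in the cold. Of 16 de novo lipogenesis genes 8 fell and 0 rose (12 down when adjusted over the list alone). The median was -0.47 (camera adjusted p = 3.07e-13, and adjusted p = 0.258 with an estimated correlation). Among them were Scd2 (28269 ± 1579 to 11308 ± 601, -1.32 ± 0.07, adjusted p = 0.000114) and Elovl6 (34148 ± 1402 to 15492 ± 1651, -1.14 ± 0.13, adjusted p = 0.00180). Of 20 cholesterol synthesis genes 15 fell and 1 rose (17 and 1 when adjusted over the list alone). The median was -0.80 (camera adjusted p = 2.34e-16, and adjusted p = 0.0700 with an estimated correlation). Examples were Fdft1, the squalene synthase (1658 ± 36.9 to 708 ± 24.3, -1.23 ± 0.07, adjusted p = 0.000175), and Sc5d (-1.05 ± 0.09, adjusted p = 0.000617). The kinase gene Pdk4, which holds back glucose oxidation, rose from 1359 ± 57.6 to 7357 ± 2446 (2.39 ± 0.19, adjusted p = 0.000559). Inmt rose from 83.3 ± 0.268 to 551 ± 114 (2.69 ± 0.13, adjusted p = 7.62e-05). The gene Cyp1a1 fell from 59.6 ± 13.7 to 3.41 ± 0.998 (-3.78 ± 0.25, adjusted p = 0.000218). Angptl8, an insulin-induced inhibitor of lipoprotein lipase, fell from 609.5 ± 51.7 to 216 ± 2.39 (-1.49 ± 0.14, adjusted p = 0.000799).

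Macrophage genes rose with cold in KO, 9 of 17 with 0 down (14 when adjusted over the list alone). The median was 1.15 (camera adjusted p = 3.33e-12, and adjusted p = 0.258 with an estimated correlation). Gpnmb rose from 58.8 ± 9.43 to 203 ± 10.7 (1.78 ± 0.15, adjusted p = 0.000643) and the phagocytic receptor gene Mertk from 215 ± 5.94 to 376 ± 12.1 (0.80 ± 0.08, adjusted p = 0.00119). Extracellular matrix genes rose, 6 of 20 with 0 down (9 when adjusted over the list alone). The median was 0.26 (camera adjusted p = 1.98e-07, and adjusted p = 0.258 with an estimated correlation). Examples were Mmp2 (0.97 ± 0.10, adjusted p = 0.00153) and Dcn (0.87 ± 0.11, adjusted p = 0.00338). The lymphocyte list passed with 0 members called (median 0.30, camera adjusted p = 0.0273, and adjusted p = 0.627 with an estimated correlation), but not without KO RT 2 (0.207), without KO Cold 1 (0.0980) or with scaling to the library total (0.179). The muscle list passed with 0 members called (median 2.42, camera adjusted p = 0.0322, and adjusted p = 0.627 with an estimated correlation). It did not pass without KO RT 1 (0.0770), KO RT 2 (0.0738) or KO Cold 1 (0.841), or with scaling to the library total (0.413). The epithelium list passed with 0 members called (median -2.65, camera adjusted p = 0.00725, and adjusted p = 0.627 with an estimated correlation), but not without KO RT 2 (0.0749). With fry the lymphocyte (0.589), muscle (0.589) and epithelium lists (0.571) did not pass. Ketone genes (2 up, 0 down, adjusted p = 0.193) and endothelial genes (1 up, 0 down, adjusted p = 0.0632) did not pass as lists, but did when KO Cold 1 was left out (0.0416 and 0.0101). Mature adipocyte genes (3 up, 4 down, adjusted p = 0.171), erythroid genes (0 called, adjusted p = 0.177) and creatine and calcium cycling genes (0 called, adjusted p = 0.409) did not pass. The cold changes of CTL and KO shared 175 genes up in both, 125 down in both, 204 up in CTL and down in KO, and 91 down in CTL and up in KO, where independent lists would share 98.6, 84.1, 112 and 74.1.

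**Figure D1:**
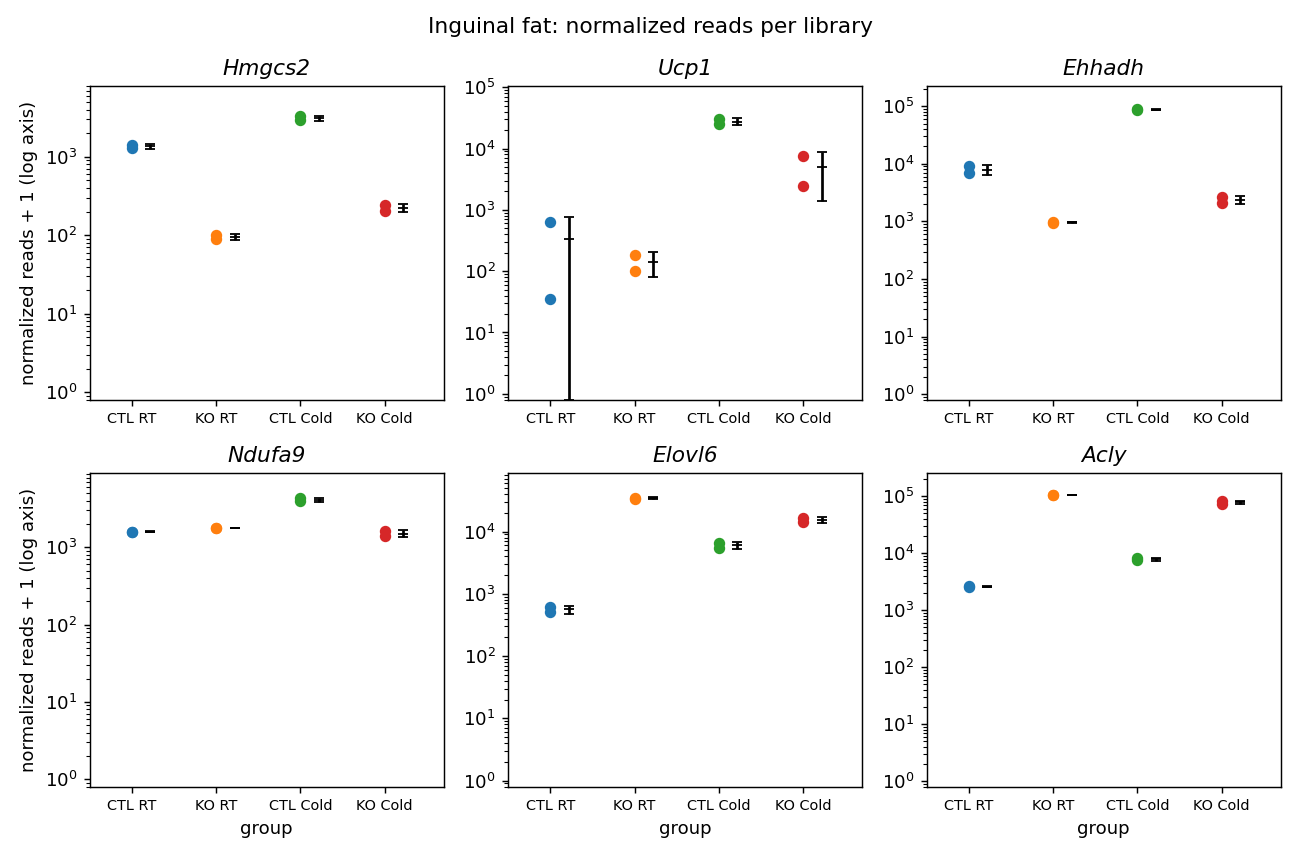
Normalized reads + 1 on a log axis for 6 genes in the 4 iWAT groups. Points are libraries (2 per group) and bars beside them are mean ± SD, ending at the lower axis limit where they pass it: Ucp1 reached 27486 in CTL Cold and 5085 in KO Cold, and Acly 105410.0 in KO RT and 2568 in CTL RT.

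At RT, lipid synthesis genes were higher in KO fat. Every measured gene of fatty acid synthesis and of cholesterol synthesis was higher than in CTL, and the leptin gene was raised. Lower in KO were 14 of 23 fatty acid oxidation genes (2 higher), 10 of 15 lipolysis (1 higher), 13 of 17 macrophage, 8 of 13 endothelial and 5 of 6 erythroid genes, and 12 of 18 lymphocyte genes were higher. None of these lists passed with an estimated correlation (adjusted p of 0.0722 for cholesterol synthesis, 0.268 for lipogenesis and 0.594 to 0.646 for the others). With fry lymphocytes did not pass (0.0639), while the lipogenesis and cholesterol lists did (adjusted p = 1.76e-05 each). Of 17187 genes, 3265 were higher and 3645 lower in KO, or 2576 and 4508 with scaling to the library total, which moves the median of all genes to -0.09. The count was 4263 without KO RT 1.

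All 16 de novo lipogenesis genes were higher in KO at RT (median 3.35, camera adjusted p = 3.39e-18, and adjusted p = 0.268 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA from citrate (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000), stood at 105410.0 ± 1466 against 2568 ± 59.6 (5.36 ± 0.08, adjusted p = 2.75e-09). Thrsp was at 31932 ± 1437 against 1625 ± 51.7 (4.30 ± 0.08, adjusted p = 5.51e-09), Scd2 at 4.70 ± 0.07 (adjusted p = 2.75e-09) and Acss2 at 5.0 ± 0.07 (adjusted p = 2.75e-09). All 20 cholesterol synthesis genes were higher (median 2.25, camera adjusted p = 2.17e-16, and adjusted p = 0.0722 with an estimated correlation). Sc5d was at 6909.6 ± 649 against 855 ± 69.6 (3.01 ± 0.09, adjusted p = 8.90e-08) and Insig1 at 2.59 ± 0.09 (adjusted p = 2.45e-07). The fructose carrier gene Slc2a5 went from 1.75 ± 1.24 to 859 ± 6.21 (8.36 ± 0.28, adjusted p = 1.68e-07). Ppp1r3b of glycogen storage went from 102 ± 3.97 to 5487 ± 23.3 (5.73 ± 0.11, adjusted p = 1.04e-08), and the prostaglandin receptor gene Ptger3 from 52.6 ± 6.32 to 2773 ± 224 (5.70 ± 0.11, adjusted p = 9.42e-09).

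The mature adipocyte list was split at RT, with 7 genes higher and 12 lower in KO (median -0.54, camera adjusted p = 0.164, or 0.0397 without CTL RT 1). Lep was at 3932 ± 229 against 119 ± 22.0 (5.04 ± 0.22, adjusted p = 7.12e-07). Dgat2 of triglyceride synthesis was at 20062 ± 1011 against 1955 ± 125 (3.36 ± 0.09, adjusted p = 4.53e-08). The lipid droplet gene Cidec was lower, 5909 ± 208 against 51620.5 ± 10069.6 (-3.11 ± 0.12, adjusted p = 3.22e-07). Fatty acid oxidation had 2 up and 14 down (median -0.51, camera adjusted p = 0.000416, and adjusted p = 0.646 with an estimated correlation). Ehhadh was at 956 ± 15.0 against 7932 ± 1598 (-3.04 ± 0.14, adjusted p = 1.01e-06). Lipolysis and adrenergic genes had 1 up and 10 down (median -0.70, camera adjusted p = 0.000278, and adjusted p = 0.594 with an estimated correlation). Nr4a3 was at 66.1 ± 11.6 against 1180.0 ± 202 (-4.14 ± 0.14, adjusted p = 2.13e-07) and Adrb2 at -2.09 ± 0.10 (adjusted p = 1.28e-06). Thermogenic genes did not pass as a list (3 up, 7 down, median -0.54, adjusted p = 0.214, or 0.0379 without CTL RT 2), with Clstn3 at -1.63 ± 0.14 (adjusted p = 4.21e-05). Ucp1 did not pass (-0.14 ± 1.11, adjusted p = 0.931), and its direction hung on CTL RT, at 1.95 without CTL RT 1 (adjusted p = 0.0138) and -2.23 without CTL RT 2 (adjusted p = 0.00923). The ketone list had 5 up and 4 down (median 0.17, mean -0.36, the test's direction down, adjusted p = 0.952), with Hmgcl (-0.90 ± 0.09, adjusted p = 7.20e-05) and the β-hydroxybutyrate receptor gene Hcar2 lower (-1.27 ± 0.15, adjusted p = 0.000246). The knocked-out Hmgcs2 is itself among the lower members of the ketone list and pulls its mean down. Oxidative phosphorylation had 6 up and 2 down (adjusted p = 0.138), and creatine and calcium cycling 3 up and 2 down (median -0.23, mean 0.13, adjusted p = 0.952).

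Immune and vascular genes differed between KO and CTL at RT. Macrophage genes were lower, 13 of 17 with 0 higher (median -1.45, camera adjusted p = 2.12e-06, and adjusted p = 0.597 with an estimated correlation). Examples were Gpnmb (58.8 ± 9.43 against 619.6 ± 42.4, -3.38 ± 0.15, adjusted p = 7.37e-07) and Mertk (-2.03 ± 0.08, adjusted p = 3.54e-07). T and B lymphocyte genes were higher, 12 of 18 with 0 lower (16 when adjusted over the list alone). The median was 1.07 (camera adjusted p = 2.32e-05, and adjusted p = 0.646 with an estimated correlation). Cr2, a complement receptor of B cells, was among them (1077 ± 49.5 against 255 ± 104, 2.13 ± 0.22, adjusted p = 0.000109). Summed normalized reads of the lymphocyte list were 14702.5 and 6845 in CTL RT and 21898 and 21248 in KO RT. Different amounts of lymph node in the samples were not tested as a source of the lymphocyte differences. The IgE constant gene Ighe had 0 reads in both CTL RT libraries and 309.9 ± 119 in KO, at least 118-fold higher (adjusted p = 7.89e-07). The neutrophil granule genes Ngp (999.7 ± 577 against 2.62 ± 3.71, 8.51 ± 1.35, adjusted p = 0.00129) and Camp (344 ± 20.3 against 1.75 ± 1.23, 7.04 ± 0.92, adjusted p = 0.000443) were higher. Endothelial genes were lower, 8 of 13 with 0 higher (median -0.54, camera adjusted p = 0.000416, and adjusted p = 0.646 with an estimated correlation). Tek was at -1.12 ± 0.08 (adjusted p = 1.46e-05). Erythroid genes were lower as well, 5 of 6 (median -1.19, camera adjusted p = 0.00896, and adjusted p = 0.646 with an estimated correlation). With fry the lymphocyte list did not pass (0.0639). Extracellular matrix genes were split (10 up, 6 down, adjusted p = 0.138), with Col6a3 higher (1.99 ± 0.10, adjusted p = 1.69e-06) and Lox lower (-2.06 ± 0.07, adjusted p = 1.37e-07).

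The skeletal muscle list passed downward in KO at RT with 1 of its 15 genes called (0 when adjusted over the list alone). The median was -4.62 (camera adjusted p = 0.0297, and adjusted p = 0.858 with an estimated correlation). The list did not pass without CTL RT 1 (0.0580), KO RT 1 (0.0533) or KO RT 2 (0.0607), with scaling to the library total (0.115), with DESeq2 (0.0923) or with fry (0.307). The muscle gene Trim63 had 0 reads in KO RT and 248 ± 14.3 in CTL RT, at least 85.8-fold lower in KO (adjusted p = 0.00219). Acta1 likewise had 1135 and 1045 reads in CTL RT and 6 and 11 in KO RT. Different amounts of muscle tissue in the samples were not tested as a source of these differences. The epithelium list had 0 called (adjusted p = 0.952), with a call downward without CTL RT 1 (0.0113) and upward without CTL RT 2 (0.00276). Inmt was lower in KO (83.3 ± 0.268 against 4367 ± 165, -5.69 ± 0.13, adjusted p = 2.03e-08), and so was Cyp2b10, a lipid and drug oxidase (10.1 ± 0.466 against 722 ± 114, -6.02 ± 0.35, adjusted p = 3.32e-06). Another large fall was that of Prg4 (62.1 ± 2.01 against 2629.8 ± 62.9, -5.38 ± 0.09, adjusted p = 4.36e-09).

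In the cold, most oxidative genes were lower in KO than in CTL fat, and 13 of 16 lipogenesis and 15 of 20 cholesterol genes were higher (2 lower in each). Lower were 16 of 25 thermogenic (1 higher), 22 of 23 fatty acid oxidation and 35 of 36 respiratory chain genes, and higher were all 18 T and B cell genes. No list passed with an estimated correlation (adjusted p of 0.431 to 0.441 for those named here). The genes of leptin, of the receptors Hcar1 and Adrb3 and of the IgA constant region were higher. Of 17187 genes, 5004 were higher and 5182 lower in KO, or 9920 and 2322 with scaling to the library total, which moves the median of all genes to 0.63. Without each library in turn the count stayed between 7964 and 9025. The KO effects at RT and in the cold shared 2208 genes up in both, 2642 down in both, 305 up at RT and down in the cold, and 166 down and up, where independent lists would share 951, 1099, 984 and 1061.

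Thermogenic genes were lower in KO in the cold, 16 of 25 with 1 higher (median -2.12, camera adjusted p = 0.000131, and adjusted p = 0.441 with an estimated correlation). With scaling to the library total 15 were lower and 3 higher. Clstn3 was at 862 ± 209 against 6279.8 ± 111 (-2.89 ± 0.14, adjusted p = 5.68e-07) and Cox8b at 455 ± 112 against 2054 ± 156 (-2.19 ± 0.18, adjusted p = 1.11e-05). Ppargc1a, the coactivator of mitochondrial biogenesis, was at 272 ± 65.3 against 1003 ± 32.9 (-1.90 ± 0.15, adjusted p = 1.16e-05). Ucp1 did not pass, at 5085 ± 3690.0 against 27486 ± 3589.6 (-2.65 ± 1.11, adjusted p = 0.0663). It passed with edgeR, the tool fixed beforehand (adjusted p = 0.0351 and 0.0390 with the 2 sets of factors). Ucp1 also passed in a model of the 2 groups alone (0.00247).

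Fatty acid oxidation genes were lower in KO in the cold, 22 of 23 with 0 higher (median -1.86, camera adjusted p = 4.31e-11, and adjusted p = 0.431 with an estimated correlation). Ehhadh was at 2389.6 ± 408 against 87236 ± 2635 (-5.20 ± 0.14, adjusted p = 2.34e-08), Acox1 at -2.20 ± 0.11 (adjusted p = 5.45e-07) and Etfa at -1.83 ± 0.09 (adjusted p = 5.14e-07). Of 36 oxidative phosphorylation genes 35 were lower and 0 higher (1 up and 35 down when adjusted over the list alone). The median was -1.24 (camera adjusted p = 3.26e-14, and adjusted p = 0.431 with an estimated correlation). Ndufv1 of complex I was among them (1866 ± 255 against 5779 ± 291, -1.64 ± 0.09, adjusted p = 1.22e-06). With scaling to the library total 21 of 23 and 34 of 36 were lower. Lipolysis and adrenergic genes had 1 up and 11 down (median -1.22, camera adjusted p = 0.00116, and adjusted p = 0.431 with an estimated correlation). With scaling to the library total 5 were up and 9 down. Nr4a3 was at 99.3 ± 7.64 against 25035 ± 799.6 (-7.96 ± 0.14, adjusted p = 6.00e-09) and Adrb2 at -3.36 ± 0.10 (adjusted p = 4.16e-08). Mfsd2a (6.46 ± 0.192 against 3237 ± 79.8, -8.76 ± 0.25, adjusted p = 2.89e-08), Cyp2b10 (-8.03 ± 0.35, adjusted p = 2.60e-07) and Hgd (-7.62 ± 0.39, adjusted p = 6.22e-07) were lower. The fatty acid hydroxylase gene Cyp4a10 had 0 reads in KO Cold and 305 ± 28.2 in CTL Cold, at least 118-fold lower (adjusted p = 6.38e-06), and so had Pah of phenylalanine breakdown with 167 ± 21.8, at least 64.6-fold lower (adjusted p = 1.24e-06).

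Lipid synthesis stayed higher in KO in the cold, with 13 of 16 de novo lipogenesis genes up and 2 down (13 and 3 when adjusted over the list alone). The median was 1.40 (camera adjusted p = 9.15e-06, and adjusted p = 0.431 with an estimated correlation). Thrsp was at 26764 ± 2155 against 2023 ± 74.8 (3.72 ± 0.08, adjusted p = 8.11e-09) and Acly at 77635 ± 4864 against 7755 ± 433 (3.32 ± 0.08, adjusted p = 1.38e-08). Of 20 cholesterol synthesis genes 15 were up and 2 down (15 and 3 when adjusted over the list alone). The median was 1.06 (camera adjusted p = 0.000131, and adjusted p = 0.431 with an estimated correlation). Ldlr, the LDL receptor gene, was up (732 ± 51.3 against 79.3 ± 0.207, 3.19 ± 0.15, adjusted p = 3.66e-07) and Cyp51 down (1415 ± 97.3 against 6647 ± 51.3, -2.23 ± 0.11, adjusted p = 4.09e-07). Lep (1318 ± 178 against 16.8 ± 6.06, 6.24 ± 0.22, adjusted p = 8.57e-08), Hcar1 (1282 ± 40.1 against 30.3 ± 13.2, 5.43 ± 0.24, adjusted p = 2.60e-07) and Adrb3 (2300.4 ± 145 against 186 ± 10, 3.62 ± 0.11, adjusted p = 4.69e-08) were higher. The mature adipocyte list as a whole was split, 6 up and 10 down with a median of -0.33 and a mean of 0.20 (adjusted p = 0.769), or 10 and 5 with a median of 0.28 under scaling to the library total. Ketone genes were split too (4 up, 5 down with the knocked-out Hmgcs2 among them, adjusted p = 0.563), with Acat1 at -1.24 ± 0.10 (adjusted p = 8.31e-06). The median of -0.18 of the ketone list became 0.42 with that scaling. Creatine and calcium cycling genes had 3 up and 4 down (adjusted p = 0.769).

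All 18 T and B lymphocyte genes were higher in KO in the cold (median 2.01, camera adjusted p = 2.82e-07, and adjusted p = 0.431 with an estimated correlation). Examples were Cr2 (1396 ± 55.9 against 176 ± 3.72, 2.98 ± 0.22, adjusted p = 6.32e-06) and Cd3d (1.70 ± 0.17, adjusted p = 3.86e-05). Lymph node in the samples was not tested as a source here either. The IgA constant gene Igha was at 1484 ± 245 against 35.8 ± 7.24 (5.34 ± 0.27, adjusted p = 5.92e-07), and Ptprc had 7866 and 7318 reads in KO Cold. Extracellular matrix genes had 12 up and 5 down (13 and 5 when adjusted over the list alone). The median was 0.60 (camera adjusted p = 0.00363, and adjusted p = 0.431 with an estimated correlation), a call lost with scaling to the library total (0.0747). Col1a1 was at 13756 ± 440.3 against 3839 ± 595 (1.85 ± 0.10, adjusted p = 1.21e-06). Endothelial genes had 0 up and 11 down (median -0.58, camera adjusted p = 0.000820, and adjusted p = 0.441 with an estimated correlation), but 1 up and 4 down with a median of 0.03 under scaling to the library total. Erythroid genes were lower, 6 of 6 (median -1.44, camera adjusted p = 0.00283, and adjusted p = 0.431 with an estimated correlation). Macrophage genes were split (5 up, 5 down, adjusted p = 0.986), with Mertk (-1.62 ± 0.08, adjusted p = 5.13e-07) and Clec4d (-4.34 ± 0.43, adjusted p = 3.86e-05) lower and Fcgr1 higher (1.77 ± 0.34, adjusted p = 0.00201). The epithelium list (1 up, 1 down, median 0.71, mean -0.07, adjusted p = 0.859) and the muscle list (0 called, median -0.73, adjusted p = 0.957) did not pass. Without CTL Cold 1 the muscle list was called upward (0.0101) and without CTL Cold 2 downward (0.00374). Mitochondrially encoded reads were 9.32% and 10.1% of KO Cold libraries and 11.8% and 12.8% of KO RT libraries.

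**Figure D2:**
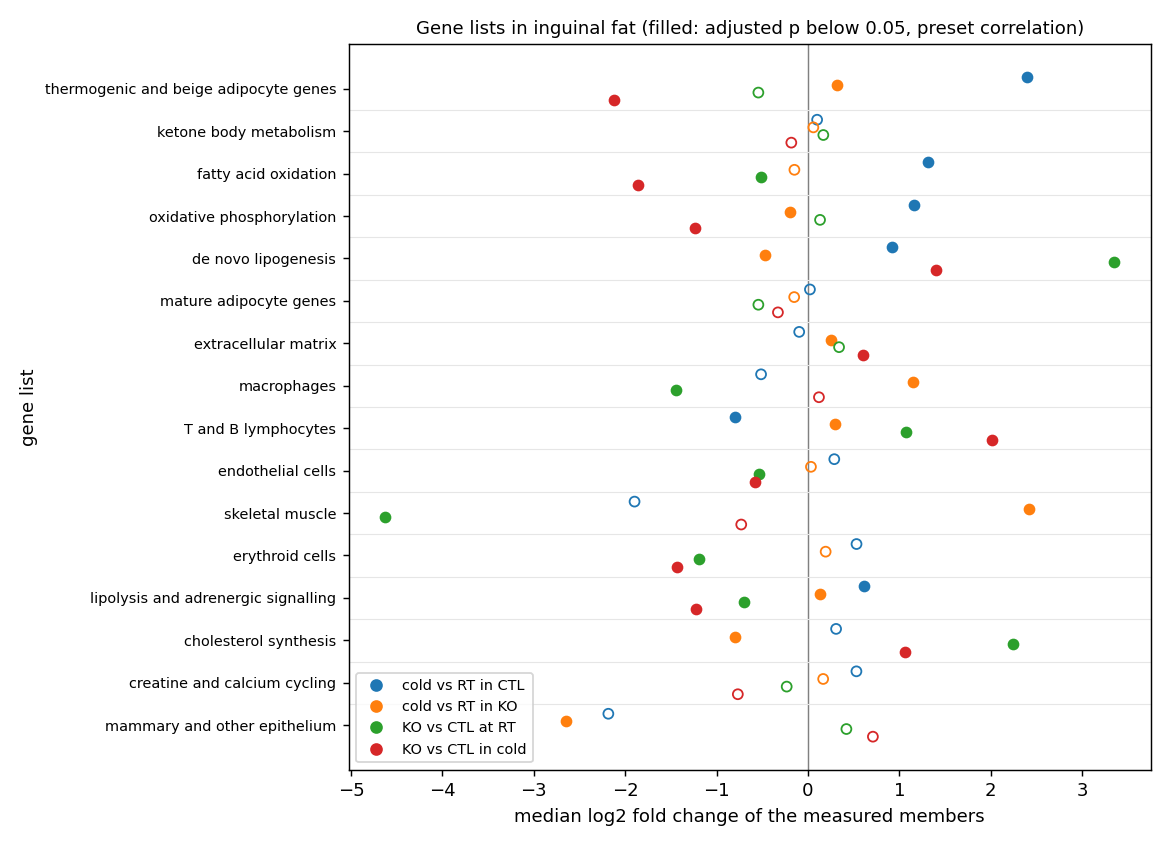
Median log2 fold change of the measured members (horizontal axis) of 16 gene lists (vertical axis) in 4 iWAT comparisons, filled where camera's adjusted p with the preset correlation passed. De novo lipogenesis sits at 3.35 for KO against CTL at RT and fatty acid oxidation at -1.86 for KO against CTL in the cold, while endothelial cells in the cold (-0.58) move to 0.03 and mature adipocyte genes in CTL (0.02) to -0.56 with scaling to the library total.

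The cold response itself differed between genotypes. A lower response in KO was called for 35 of 36 respiratory chain, 19 of 23 fatty acid oxidation (1 higher), 13 of 25 thermogenic (1 higher), 15 of 16 lipogenesis and 13 of 20 cholesterol genes (2 higher). A higher one was called for 14 of 17 macrophage and 6 of 18 lymphocyte genes. With an estimated correlation none of these lists passed (adjusted p of 0.369 to 0.597), and the lymphocyte list was also lost with fry (0.173) and with scaling to the library total (0.0577). The interaction was higher for 2087 genes and lower for 3128, or 9097 and 985 with scaling to the library total, which moves the median of all genes to 0.73. The count was 3438 without KO RT 2 and 3325 without KO Cold 1.

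Of 36 oxidative phosphorylation genes, 35 had a lower cold response in KO and 0 a higher one (median -1.36, camera adjusted p = 4.30e-22, and adjusted p = 0.369 with an estimated correlation). Ndufa9 was among them (-1.63 ± 0.11, adjusted p = 2.33e-05). Fatty acid oxidation had 1 higher and 19 lower (1 and 22 when adjusted over the list alone). The median was -1.43 (camera adjusted p = 5.38e-12, and adjusted p = 0.369 with an estimated correlation). Acaa2 was at -2.89 ± 0.23 (adjusted p = 5.67e-05). Thermogenic genes had 1 higher and 13 lower (1 and 16 when adjusted over the list alone). The median was -1.89 (camera adjusted p = 8.23e-05, and adjusted p = 0.597 with an estimated correlation). Cox8b was at -2.23 ± 0.25 (adjusted p = 0.000305). De novo lipogenesis had 0 higher and 15 lower (median -1.47, camera adjusted p = 5.14e-12, and adjusted p = 0.369 with an estimated correlation). Elovl6 was at -4.57 ± 0.18 (adjusted p = 3.37e-06). Cholesterol synthesis had 2 higher and 13 lower (2 and 14 when adjusted over the list alone). The median was -1.10 (camera adjusted p = 5.86e-06, and adjusted p = 0.369 with an estimated correlation). Cyp51 was at -2.99 ± 0.15 (adjusted p = 6.72e-06). With fry the thermogenic list did not pass (0.0571). These 5 medians kept their sign with scaling to the library total. Ucp1 did not pass (-2.51 ± 1.56, adjusted p = 0.263), and hung on CTL RT, at -4.60 without CTL RT 1 (adjusted p = 0.000752) and -0.41 without CTL RT 2 (adjusted p = 0.679).

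Macrophage genes had 14 of 17 higher and 0 lower in the interaction (median 1.84, camera adjusted p = 5.86e-06, and adjusted p = 0.450 with an estimated correlation). Gpnmb was at 2.83 ± 0.21 (adjusted p = 3.47e-05). Lymphocyte genes had 6 higher and 0 lower (9 when adjusted over the list alone). The median was 0.98 (camera adjusted p = 0.000120, and adjusted p = 0.597 with an estimated correlation), a call lost with scaling to the library total (0.0577) and with fry (0.173). Matrix genes had 7 higher and 0 lower (median 0.27, camera adjusted p = 0.00145, and adjusted p = 0.369 with an estimated correlation). Among single genes, Mfsd2a (-6.60 ± 0.36, adjusted p = 7.42e-06) and Nr4a3 (-3.83 ± 0.20, adjusted p = 7.42e-06) had lower cold responses in KO. Those of Ffar2 (4.58 ± 0.20, adjusted p = 5.41e-06), Hcar1 (4.23 ± 0.33, adjusted p = 4.79e-05) and Adrb3 (3.17 ± 0.16, adjusted p = 6.93e-06), which fell in CTL, were higher in KO. Lists that did not pass were lipolysis (3 higher, 8 lower, adjusted p = 0.0864, or 6 and 3 with scaling to the library total), muscle (0.0626), creatine and calcium cycling (0.240), erythroid (0.260), endothelial (0.478), mature adipocyte (0.565), ketone (0.605) and epithelium (0.796). The epithelium list was called downward without CTL RT 2 (0.0375) and with scaling to the library total (0.0221), and upward without CTL RT 1 (0.00502). Also with 1 library left out, the muscle list passed without CTL Cold 1 (1.43e-06) or KO Cold 2 (0.00328), the lipolysis list without KO Cold 2 (0.0190) and the endothelial list without CTL RT 2 (0.0207).

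In SVF, 1,3BD raised 9 of 11 measured adipocyte genes and lowered 6 of 10 pericyte and smooth muscle, 10 of 20 matrix and 18 of 36 respiratory chain genes. None of these lists passed with an estimated correlation (adjusted p of 0.569 to 0.866), nor did the respiratory chain list with fry (0.0564). Fabp4 and Plin1 rose from low levels and Lpl from a higher one, and smooth muscle actin and connective tissue growth factor fell. The sources used here do not say whether these cells were cultured, sorted or differentiated before RNA isolation, so each SVF value holds for the cells as sequenced. Of 13857 genes, 3399 rose and 3451 fell with 1,3BD, or 4395 and 2527 with scaling to the library total, which moves the median of all genes to 0.16. Replicate 3 of the 1,3BD group stood apart, with 5188 Fabp4 reads against 20197 and 35262, and without it 7347 genes were called. Water 3 stood apart as well, with summed normalized reads of immediate early genes of 18937.5 against 7330.2 and 8139 in the other water libraries and 1519 Acta1 reads against 506 and 526, and without it 6426 genes were called. The immediate early sum was also higher in 1,3BD 3, at 14537 against 6353 and 6042 in the other 1,3BD libraries, so both libraries numbered 3 share this feature. Mitochondrially encoded reads were 3.37%, 3.56% and 2.82% of 1,3BD libraries and 0.925%, 0.932% and 1.18% of water libraries. The leukocyte gene Ptprc had at most 4 reads in any SVF library, and the endothelial gene Pecam1 had 18 to 32. Of the lists, 1 of 18 lymphocyte, 0 of 11 neutrophil and 7 of 17 macrophage genes passed the filter. Leukocyte and endothelial transcripts were thus scarce, and the values may not hold for the whole fraction in the animal.

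Of 11 mature adipocyte genes measured, 9 rose and 0 fell (median 2.21, camera adjusted p = 0.00229, and adjusted p = 0.676 with an estimated correlation). The other members of this list of 20 were too low to test. Among them, means of Adipoq, Cidec, Retn, Gpd1, Aqp7 and Slc2a4 were higher with 1,3BD, and those of Cfd, Lep and Pck1 lower. Adipoq had 0, 3 and 0 reads in water and 107, 322 and 0 with 1,3BD. Cfd had 14, 9 and 2 reads in water and 2, 3 and 0 with 1,3BD. Fabp4, a fatty acid carrier of adipocytes (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576), rose from 118 ± 22.8 to 18330.2 ± 13286 (6.91 ± 0.58, adjusted p = 0.000112). The droplet coat gene Plin1 rose from 3.66 ± 1.51 to 732 ± 646 (6.62 ± 0.89, adjusted p = 0.000779) and Lpl from 5599 ± 1018 to 64657 ± 34763 (3.38 ± 0.39, adjusted p = 0.000443). Pparg, the master regulator of adipogenesis, rose from 170.1 ± 5.62 to 856 ± 374 (2.21 ± 0.32, adjusted p = 0.00102). The transcription factor gene Zbtb16 had 0 reads in the 3 water libraries and 1368 ± 558 with 1,3BD, at least 424-fold higher (adjusted p = 6.35e-06). Prg4 rose from 27.8 ± 6.6 to 3217 ± 731 (6.80 ± 0.24, adjusted p = 6.35e-06) and Serpina3n from 43.5 ± 43.1 to 2822 ± 1876 (6.10 ± 0.75, adjusted p = 0.000537).

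The pericyte and smooth muscle list fell, 6 of 10 with 0 up (7 when adjusted over the list alone). The median was -2.93 (camera adjusted p = 0.00249, and adjusted p = 0.569 with an estimated correlation). Examples were Cnn1 (4413 ± 2564 to 172 ± 84.4, -4.68 ± 0.48, adjusted p = 0.000252) and Lmod1 (-3.87 ± 0.45, adjusted p = 0.000418). Beige adipocyte progenitor genes fell, 6 of 9 with 0 up (median -0.49, camera adjusted p = 0.0224, and adjusted p = 0.569 with an estimated correlation). Acta2, smooth muscle actin, fell from 95123 ± 38471 to 2623 ± 672 (-5.14 ± 0.29, adjusted p = 3.05e-05) and Pdgfrb from 12508 ± 3061 to 3425 ± 585 (-1.85 ± 0.22, adjusted p = 0.000486). Acta2 and Myh11 of this list are smooth muscle genes, so its call cannot be told apart from the smooth muscle fall. Its member Pdgfra was not called, with normalized reads of 5976, 5490 and 4187 in water and 6871, 7104 and 5037 with 1,3BD. Of 20 extracellular matrix genes 10 fell and 0 rose (median -0.83, camera adjusted p = 0.00407, and adjusted p = 0.676 with an estimated correlation). Ctgf fell from 6936 ± 2095 to 98.3 ± 32.6 (-6.14 ± 0.28, adjusted p = 2.41e-05). The gap junction gene Gjb2 fell from 332 ± 92.8 to 1.85 ± 2.45 (-7.20 ± 0.58, adjusted p = 9.34e-05) and the cadherin gene Cdh3 from 1876 ± 649.9 to 23.6 ± 8.81 (-6.24 ± 0.33, adjusted p = 2.41e-05). Endothelial genes fell, 5 of 6 (median -1.59, camera adjusted p = 0.0418, and adjusted p = 0.569 with an estimated correlation), a call lost with DESeq2 (0.0910), with TMM scaling (0.0516) and without water 3 (0.0695). The list has 13 members, and levels of the 6 measured ones were low. They summed to 1195, 1057 and 1248 normalized reads in water and 387, 373 and 412 with 1,3BD. Pecam1 had 29, 30 and 32 reads in water and 22, 18 and 18 with 1,3BD.

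Oxidative phosphorylation genes fell in SVF, 18 of 36 with 1 up (20 and 1 when adjusted over the list alone). The median was -0.38 (camera adjusted p = 0.00249, and adjusted p = 0.866 with an estimated correlation). With scaling to the library total 10 were down and 5 up. The oxidative phosphorylation list did not pass with fry (0.0564). Ndufs8 fell from 749.7 ± 126 to 282 ± 10.7 (-1.40 ± 0.16, adjusted p = 0.000460). Thermogenic genes did not pass (4 up, 3 down of 13, adjusted p = 0.810). Dio2 went from 0.320 ± 0.555, or 1 read in all, to 36.6 ± 10.1 (adjusted p = 0.000214), a ratio of 114 with a counting interval of 18.0 to 4067. Lhx8 rose by 1.74 ± 0.18 (adjusted p = 0.000272), and the fatty acid carrier gene Fabp3 fell by 3.80 ± 0.32 (adjusted p = 0.000109). Ucp1 in SVF is not analysed here. Hmgcs2 did not pass (6.27 ± 8.08 to 40.9 ± 31.9, 2.76 ± 1.13, adjusted p = 0.0720), with 0, 3 and 16 reads in water and 53, 76 and 6 with 1,3BD. It passed without water 3 (0.0283) and without 1,3BD 3 (0.00637). The ketone list had 2 up and 3 down (adjusted p = 0.850), with Slc16a1 up (745 ± 151 to 3615 ± 2067, 2.15 ± 0.34, adjusted p = 0.00159) and Bdh2 down (-2.02 ± 0.22, adjusted p = 0.000352). Fatty acid oxidation (5 up, 3 down, adjusted p = 0.907) and de novo lipogenesis (2 up, 4 down, adjusted p = 0.810, with Scd1 at 2.31 ± 0.38, adjusted p = 0.00181) did not pass.

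Progenitor lists outside the beige one were split in SVF, and more cell cycle genes fell than rose. Dpp4-positive progenitor genes had 2 up and 4 down of 8 (adjusted p = 0.332) and Icam1-positive and F3-positive preadipocyte genes 4 up and 5 down of 11 (adjusted p = 0.707). Of the latter, Clec11a fell (-3.66 ± 0.25, adjusted p = 5.48e-05) and Fmo2 rose (2.60 ± 0.52, adjusted p = 0.00416). Cell cycle genes had 1 up and 12 down of 23 (adjusted p = 0.0852), and passed as a list without water 2 (0.0427) or 1,3BD 2 (0.0269). The mitotic kinase gene Plk1 fell (652 ± 31.7 to 209 ± 12.5, -1.63 ± 0.14, adjusted p = 0.000117) and Rrm2 of nucleotide synthesis rose (996 ± 174 to 2821 ± 359, 1.51 ± 0.17, adjusted p = 0.000347). Immediate early genes had 0 up and 4 down of 17 (adjusted p = 0.140, or 0.0191 without 1,3BD 3). Macrophages (0 up, 2 down, adjusted p = 0.478), skeletal muscle (0 up, 2 down, adjusted p = 0.332) and Schwann cells (0 up, 2 down, adjusted p = 0.570) did not pass. Too few members were measured to test T and B lymphocytes (Lck alone, -1.95 ± 0.43, adjusted p = 0.00671), erythroid cells (Alas2 alone, 2.34 ± 0.77, adjusted p = 0.0344, but 0.0939 without 1,3BD 1 and 0.0798 without 1,3BD 2) and neutrophils (0 measured).

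**Figure D3:**
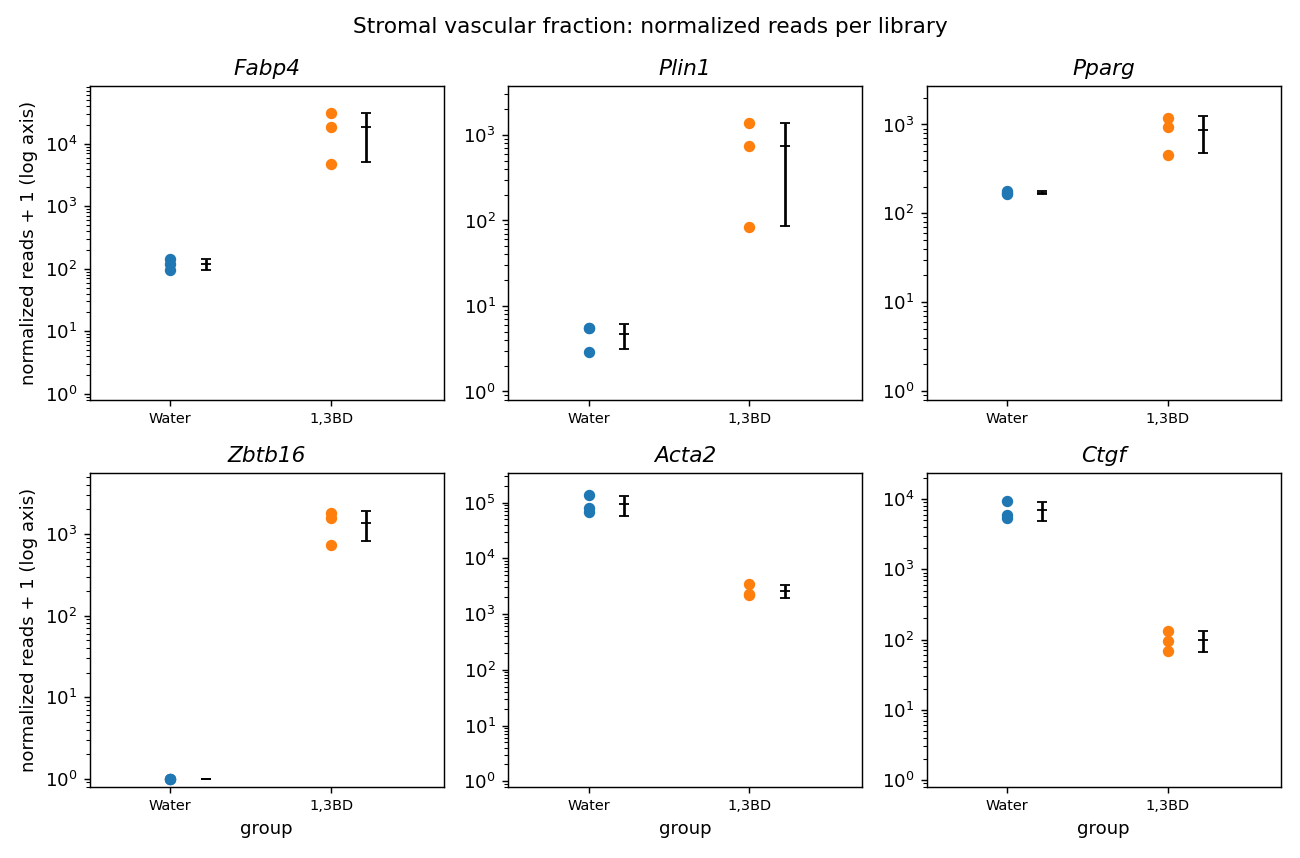
Normalized reads + 1 on a log axis for 6 genes in SVF of mice given water or 1,3BD. Points are libraries (3 per group) and bars beside them are mean ± SD: Fabp4 is at 118 in water and 18330.2 with 1,3BD, and Acta2 at 95123 and 2623.

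Some named genes overlap another annotated gene (Dio2, Elovl6, Adrb3, Acss2, Scd2, Fdft1, Lox, Prg4, Acox1, Ndufa9, Cyp51, Ctgf, Fabp3, Plk1, Lck and Alas2), and because the strand setting of counting is not given, reads of the neighbour may be included in their values. With 2 libraries per iWAT group, 1 library moves several of the counts above, as stated beside them.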

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

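The 2 tests over other groupings of the SVF libraries were fixed before their results were seen, and the other tests of explanations in this part were chosen after the patterns were seen. The genes and lists below stand out because a test of the difference itself, the genotype by temperature interaction, gave CTL and KO different responses to cold. The response was higher in KO for 2087 genes and lower for 3128. List medians of the difference were -1.89 (thermogenic and beige adipocyte genes), -1.43 (fatty acid oxidation), -1.36 (oxidative phosphorylation), -1.47 (de novo lipogenesis), -1.10 (cholesterol synthesis), 0.27 (extracellular matrix), 1.84 (macrophages) and 0.98 (T and B lymphocytes). With an estimated correlation between genes these 8 lists had adjusted p from 0.369 to 0.597.

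The named genes with the highest difference of the cold responses were Ffar2 (4.58), Cd300c (4.48), B3galt2 (4.32), Hcar1 (4.23), Oxtr (4.13), Tlr11 (3.91), Cd209g (3.84), Iglv2 (3.71), Prokr1 (3.57) and P2ry13 (3.51). Those with the lowest were Mfsd2a (-6.60), Ppp1r3g (-5.99), Orm3 (-5.97), Cend1 (-5.66), Tat (-5.51), Slc2a5 (-5.37), Cyp1a1 (-5.33), Kng2 (-5.28), Scd3 (-5.25) and Mmd2 (-5.22). Oxtr did not pass without the low-count filter (adjusted p = 0.114), nor without CTL RT 2 (0.0536), KO RT 1 (0.113), KO RT 2 (0.0960), CTL Cold 1 (0.0772), KO Cold 1 (0.114) or KO Cold 2 (0.101). Iglv2 did not pass without the filter (0.0691), nor without KO RT 2 (0.0705), CTL Cold 2 (0.0566), KO Cold 1 (0.0764) or KO Cold 2 (0.0692). With edgeR Ppp1r3g did not pass (0.938 with both sets of factors), nor did Tat (0.0631 and 0.0641). Over their alternatives the adjusted p ranged from 0.00495 to 0.114 (Oxtr), 0.00244 to 0.0764 (Iglv2), 6.95e-05 to 0.938 (Ppp1r3g) and 8.48e-05 to 0.0641 (Tat).

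Oxidative genes were lower in KO than in CTL in the cold. Scaling of the libraries as the whole cause is argued against, because the fatty acid oxidation list kept a median of -1.25 with scaling to the library total (quartiles -1.60 to -0.73, adjusted p = 6.82e-18, and 1.46e-27 to 0.431 over all alternatives, the highest with an estimated correlation). Dilution of adipocytes by lymph node or other tissue is argued against as the whole cause for the fatty acid oxidation list alone. Its median was -1.86, and that of the mature adipocyte list -0.33 (quartiles -0.85 to 0.63). The adipocyte list gauges adipocyte share only roughly, as 6 members were higher and 10 lower in KO. Its summed normalized reads were 791951 and 813079 in CTL Cold and 396004 and 436990 in KO Cold, so dilution as a part of the cause stays open. Oxidative phosphorylation genes were not set against it. A change within adipocytes of KO mice may underlie the pattern, a hypothesis that was not itself tested and that RNA from isolated adipocytes of both genotypes would test. A different hour of harvest stays open here too. In the cold all 5 clock genes that peak with Arntl were lower in KO (median -1.64). Of 7 that peak with Dbp, 2 were higher and 2 lower (median -0.45). Sex, feeding and litter, which the labels leave open, were not tested.

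Lipogenic genes were higher in KO than in CTL at RT. Scaling as the whole cause is argued against by the de novo lipogenesis list, whose median with scaling to the library total was 3.25 (lower quartile 1.65, adjusted p = 1.79e-21, and 2.54e-207 to 0.268 over all alternatives, the highest with an estimated correlation). A different hour of harvest stays open: all 5 clock genes that peak with Arntl were lower in KO, while of 7 that peak with Dbp 1 was higher and 2 lower (2 and 2 when adjusted over the list alone), and the Dbp-phase median lay 0.418 above the Arntl-phase median. Feeding before harvest was not tested, and could raise the same genes. Genotype and these conditions cannot be told apart with 2 libraries per group.

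Adipocyte and glucocorticoid-responsive genes were higher with 1,3BD in SVF, and the mature adipocyte list passed without each library in turn (highest adjusted p = 0.00465, against 0.676 with an estimated correlation). The glucocorticoid list, chosen after the results were seen, had an adjusted p of 4.46e-07, or 0.176 with an estimated correlation. Mature adipocytes carried over into the fraction cannot be told apart from other sources over the adipocyte list as a whole: scaled by Fabp4 to CTL RT tissue, its 19 other members reached a median of 16.2% of the predicted level (quartiles 4.36% to 154%). Adipocytes with the make-up of that tissue as the whole source of the Fabp4 rise are argued against, because 4 of the 8 members predicted at 1000 or more normalized reads stayed below 10% (Cfd 0.0161%, Pck1 0%, Cidec 1.26% and Adipoq 4.92%), while Lpl was at 420%. Differentiation of stromal cells, before or after isolation, is a candidate explanation that was not tested.

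Of the 10 ways to split the 6 SVF libraries into 3 and 3, which are too few for a share under 0.05, 1 gave as many genes (6850, highest other 0) and 4 gave as many lists (6, highest other 9). The other splits passed 2 to 9 lists with 0 genes called. A list can therefore pass with the preset correlation where no gene does. These splits mix water and 1,3BD libraries, so they are not free of a treatment effect.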

How the results depend on the processing

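DESeq2, edgeR, the other pseudocounts and TMM scaling kept every count of changed genes within 1.5 times of the reported 6776 (cold in CTL), 935 (cold in KO), 6910 (KO at RT), 10186 (KO in the cold), 5215 (interaction) and 6850 (SVF). Counts outside that range were 475 (cold in KO without the low-count filter), 2070 (cold in KO with only the 2 compared groups in the model), 11128 and 10082 (cold in CTL and interaction with scaling to the library total), and, at an absolute log2 fold change of at least 1, 2199, 222, 2803, 4992, 2288 and 3688. The last setting asks for larger changes, and the cause of the others was not tested. Of the lists, 6, 10, 9, 10, 8 and 6 passed. Cold in CTL had 10 with DESeq2 and 10 without the filter, SVF 10 without the filter, and cold in KO 4 with fry. With an estimated correlation camera called 0 lists in each of the 6 comparisons, where 0, 2, 2, 0, 1 and 0 had an unadjusted p under 0.05 and fry called 9, 4, 9, 12, 7 and 7. Scaling to the library total turned the direction of Lum (-0.15), Mertk (-0.18), Esam (-0.0604), Egfl7 (-0.21) and Slc6a8 (-0.16) for cold in CTL, of Robo4 (0.11) and Atp2a2 (0.18) in the interaction, and of the epithelium list there (adjusted p = 0.0221); it left 412 named-gene results as they were, with 16 no longer past the threshold and 1 newly past it. With DESeq2 426 of 436 named-gene results were the same, 5 no longer passed and 5 had no adjusted p. A change of sign where both values miss the threshold is counted as the same.

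With 1 library left out, the remaining library of that group is assumed to vary like the other groups. Counts of genes then ranged over 5133 to 6818 (cold in CTL), 206 to 314 (cold in KO), 4263 to 7023 (KO at RT), 7964 to 9025 (KO in the cold), 3325 to 6046 (interaction) and 4952 to 7347 (SVF), and lists over 7 to 9, 7 to 10, 8 to 11, 10 to 11, 8 to 10 and 5 to 7. Of named-gene results 2020 were the same, 171 no longer passed, 4 newly passed and 1 reversed: Ucp1 for KO at RT, at -2.23 to 1.95. The adjusted p of lists that reversed was 0.00276 to 0.827 for epithelium in KO at RT (reversed without CTL RT 1, 0.0113), 0.00502 to 0.972 for epithelium in the interaction (reversed without CTL RT 2, 0.0375), and 0.00374 to 0.389 for muscle in KO in the cold (reversed without CTL Cold 1, 0.0101).

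With the replicate number as a replicate block the counts were 6947, 1190, 7106, 10276, 5408 and 6851 genes and 9, 12, 9, 10, 9 and 6 lists, where all 436 named-gene results were the same and 6 list results newly passed. The labels give no origin for the numbers. Deviations of same-numbered SVF libraries correlated at 0.134, 0.0560 and 0.135, and each of the 3 water libraries correlated best with its own number, a hint from the data and not from the design. In iWAT the correlations between groups were -0.0658 to 0.291.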

Other observations

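The 6 lists in this part were written after the results were seen, so all of its tests were chosen after the fact, and genes such as Zbtb16 and Pdk4 had been seen to change before they were listed. Adjusted p are over these lists alone, with the value for an estimated correlation given second. Glucocorticoid-responsive genes were lower in KO fat, 15 of 16 with 0 higher at RT (median -2.46, adjusted p = 3.68e-14 and 0.0177) and 15 with 0 higher in the cold (median -2.97, adjusted p = 3.09e-11 and 0.0244). Fkbp5, which restrains the glucocorticoid receptor, was at -2.32 ± 0.07 (adjusted p = 1.10e-07) and -3.00 ± 0.07 (adjusted p = 1.38e-08), and Tsc22d3 at -2.76 ± 0.08 (adjusted p = 1.01e-07) and -2.82 ± 0.08 (adjusted p = 3.10e-08). Cold raised 15 of these genes in CTL and lowered 0 (median 1.45, adjusted p = 1.03e-10 and 0.0267), raised 8 and lowered 1 in KO (9 and 1 when adjusted over the list alone, median 0.46, adjusted p = 1.54e-07 and 0.102), and the interaction was lower for 9 and higher for 0 (median -0.86, adjusted p = 0.000547 and 0.158). Zbtb16 had 1154 and 1229 reads in CTL RT, 287 and 322 in KO RT, 3583 and 3837 in CTL Cold, and 216 and 185 in KO Cold. In SVF 13 of the 16 rose with 1,3BD and 0 fell (median 2.77, adjusted p = 4.46e-07 and 0.176), with Fkbp5 at 2.82 ± 0.24 (adjusted p = 0.000119). Zbtb16, at 0 in water, lies above that median at its bound too. Whether these cells were kept in a medium with a glucocorticoid is not given in the sources used here, which leaves the source of the SVF rise open.

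Genes induced by fasting and FOXO factors were lower in KO as well, with 2 higher and 11 lower of 14 at RT (median -1.52, adjusted p = 1.47e-06 and 0.0177) and 2 and 12 in the cold (median -1.81, adjusted p = 2.24e-06 and 0.0244). In CTL cold raised 9 and lowered 0 (median 0.98, adjusted p = 8.51e-06 and 0.0267), and in KO 2 and 1 (3 and 1 when adjusted over the list alone, median 0.09, adjusted p = 0.0469 and 0.186). The interaction had 3 higher and 7 lower (median -0.68, adjusted p = 0.00751 and 0.158), and in SVF 6 rose and 2 fell (adjusted p = 0.237 and 0.439). Among clock genes that peak with Arntl, cold in CTL raised 5 of 5 (median 1.16, adjusted p = 0.000185 and 0.168), and KO was lower for 5 of 5 at RT (median -0.63, adjusted p = 0.000842 and 0.170) and in the cold (median -1.64, adjusted p = 0.000294 and 0.181). Neutrophil granule genes were higher in KO, 8 of 10 with 0 lower at RT (median 4.14, adjusted p = 0.000132 and 0.170) and 8 with 1 lower in the cold (9 and 1 when adjusted over the list alone, median 3.42, adjusted p = 0.00696 and 0.314). General leukocyte genes were split at RT (3 higher and 3 lower of 8, adjusted p = 0.946 and 0.980) and higher in the cold (7 with 0 lower, median 1.20, adjusted p = 0.00360 and 0.366).

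The low glucocorticoid-responsive and fasting genes of KO fat, beside its high lipogenic genes, may reflect a fed or low-stress state of these mice at harvest. This is a hypothesis, and neither feeding nor stress was tested. The test nearest to it, the gap of 0.418 between clock genes of opposite phase at RT, leaves the hour of harvest open.

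In SVF the rRNA gene CT010467.1 took 2.55%, 2.71% and 2.01% of reads with water and 1.09%, 1.14% and 1.44% with 1,3BD. The 10 most abundant genes took 12.5% and 13.4% of reads in CTL RT, 22.1% and 23.3% in KO RT, 22.3% and 24.6% in CTL Cold, and 16.9% and 17.6% in KO Cold. Size factors were 0.717 and 0.758 in CTL Cold, against 1.02 to 1.21 in the other iWAT libraries.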
